A study of Drosophila melanogaster with 2 samples.

How the data were processed

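ChIP-seq of GFP-tagged Groucho was measured in whole Drosophila melanogaster embryos of mixed sex aged 0 to 24 h, in 2 biological replicates of 1 group. Per the labels, the chromatin was fragmented by sonication to 200 to 800 bp and precipitated with an anti-GFP antibody from a line in which gro carries a C-terminal GFP. The replicates are named 1 and 3 as in the labels, which give both the same general protocol and each a further protocol document of its own, not read here. A control alignment is named in the deposited manifest as an input to peak calling, and it was not analysed here.

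Per the deposited manifest, the authors called 1 list of 30000 regions from each replicate's alignment with the control, and 1 list of 30000 regions from both alignments pooled. From these lists they derived 1 optimal list by the irreproducible discovery rate (IDR), in the dm3 and in the dm6 build. The aligner, the peak caller and its settings, the IDR threshold and the software versions are not given in the sources used here. The signal in column 7 of each list is the value the authors deposited from their peak caller, with no scale stated. Column 9 of the deposited lists holds the −log10 of a q value, which saturates at 1 maximum per list. In the dm6 IDR list 61.1% of regions were at that maximum of 3.74, so sites were ranked by signal. Column 8 held no p-value. All 4492 IDR peaks had the interval, summit and signal of a pooled region, and they were exactly the 4492 pooled regions with the highest signal, 15.0% of that list. The pooled signal is not on the scale of the replicate signals, so replicate values are given as their own mean ± SD (n = 2). The files hold no read counts, so the depth of each library is unknown.

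Gene models came from Ensembl release 115 and the sequence from RefSeq Release 6, which is dm6. Of 13945 protein-coding genes found in both annotations, 13944 had equal coordinates, and no dm6 region ran past the end of its arm. No dm3 reference was used and no coordinates were converted; positions in the text are dm6, counted from 1. Genes on arms 2L, 2R, 3L, 3R, 4 and X were kept and transposable elements left out, which gave 13945 protein-coding genes among 18164 genes. In the dm6 lists 0 regions lay off these arms, and in the dm3 IDR list 1 did. In the dm6 IDR list 4 intervals were repeated, with separate summits, and were kept.

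Replicates were compared by the overlap, of at least 1 bp, of their 4492 highest regions, against 1000 random placements of the second list on the same arms. Signals of matched regions were compared by Spearman's and Pearson's correlation. Each summit was put in 1 of 7 classes with the priority TSS within 500 bp, 5′ UTR, CDS, 3′ UTR, other exon, intron and intergenic. The shares were compared with 1000 random placements per arm in sequence without N, by a two-sided permutation test whose smallest p is 0.002. Peaks per arm were compared with arm length by the exact binomial test. A gene counted as having a site when an IDR summit lay within 1 kb of any of its TSSs; 3612 genes (25.9%) did, and 1176 summits (26.2%) counted for more than 1 gene. Each of 27 gene lists was compared with all other protein-coding genes by Fisher's exact test, two-sided. The lists were the E(spl) complex, Notch pathway, Groucho-recruiting repressors, gap and pair-rule segmentation, segment polarity, Hox genes, dorsal-ventral patterning, Wingless pathway, EGFR and FGF pathway, Dpp pathway, proneural and neuroblast, mesoderm and muscle, trachea and ectoderm appendage, and ecdysone response. The others were Polycomb and Trithorax group, cell cycle, cytosolic ribosomal proteins, proteasome, oxidative phosphorylation, cuticle proteins, odorant and gustatory receptors, chorion and yolk, Jonah digestive proteases, germ line, hemocyte and fat body, photoreceptor, and stress response. Symbols were matched by current name or a listed synonym, and the few that repeated another listed gene or had no match were dropped; the number of genes given for each list is that of the matched genes. Peak heights of a list were compared with 10000 random lists of genes with a peak. Consensus matches of 23 motifs on either strand were counted in windows of 100 bp on each side of the summit. They were compared with the window 1000 bp downstream by the exact McNemar test. For these flanks, downstream means toward the higher coordinate and upstream toward the lower, whatever the strand of nearby genes. p-values were adjusted by Benjamini-Hochberg within the classes, arms, lists or motifs, and a result passed at an adjusted p under 0.05. Intervals of shares are Wilson 95% intervals and cover counting error alone.

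The lists, motifs, tests and most alternatives were fixed before the data were examined. So was the rule for named genes: the 25 IDR peaks of highest signal, each with the protein-coding gene of the nearest TSS; the 10 genes with most summits in the gene or within 5 kb; a panel of 48 genes, of which 43 are targets or partners of Groucho and 5 are housekeeping genes; and up to 4 members of highest signal of each list that passed. Members of the other lists were named by the same limit of 4. Genes of the 9 lists added in the closing section were chosen after seeing the data.

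Alternatives covered a stricter list (the upper part of the IDR list by signal, split at its median), each replicate alone, the overlap rule, the number of top regions (1000 and 10000, the latter with fewer placements), the ranking by q value, the build, TSS distances, gene assignment, backgrounds, motif windows, flanks and reversed motifs, and summits near or far from TSSs. Backgrounds of pooled regions and of genes without a site, all pooled regions in place of IDR peaks for gene lists, and the stricter and single-replicate lists for named genes, multi-peak genes and peak heights, were added after seeing the data. Without a replicate means that the 4492 highest regions of the other replicate took the place of the IDR list. The procedures were tested on simulated data: 94% of simulated lists of 40 genes with a share of 60% were called and 0.0769% of unchanged lists were. Smaller lists and smaller rises, for which the power is lower, were not simulated. A planted motif was recovered at 10.8% of windows with 0 other motifs called, and random summits gave a promoter enrichment of 1.02-fold. Computations used python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.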

Results

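Sites of Groucho (gro), a corepressor that DNA-binding repressors bring to their targets, were mapped by ChIP-seq in Drosophila melanogaster embryos. Chromatin came from whole embryos of mixed sex aged 0 to 24 h, from a transgenic line in which GFP is fused to the C-terminus of gro, and was precipitated with an anti-GFP antibody. The series held 1 group with 2 biological replicates, numbered 1 and 3 in the labels. The questions the design allows are where in the genome the fusion protein was recovered and how alike both replicates were; the labels name no treatment, time course or other group. The authors' reproducible list, selected with the irreproducible discovery rate (IDR), held 4492 regions in the dm6 build, and these are called IDR peaks here. The median region was 410 bp wide, and the signal value in the authors' column ran from 80.6 to 1892 with a median of 116. The scale of that signal is not stated, so it was used to describe and to rank sites within a list. The files hold regions and no read counts, so the sequencing depth is unknown; the Wilson 95% intervals given below cover counting error of sites or genes alone.

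The highest Groucho site in the embryos lay in an intron of ush, which encodes a cofactor of GATA factors, at 2L from 480841 to 481383 in dm6. Its pooled signal was 1892, its replicate signal was 947 ± 292 (SD, n = 2), and the nearest protein-coding TSS was that of cbt, 1371 bp away. Next came a promoter site at CG14100 (3L, 19590425 to 19590807) with a pooled signal of 1604 and an intronic site of CG11050 (2L, 6612388 to 6612927) with 1599; their replicate signals were 803 ± 301 and 798 ± 108 (SD, n = 2). Promoter sites at Ugalt, which encodes a nucleotide sugar transporter (X, 2703702 to 2704090, signal 1387), and at PNPase, which encodes a mitochondrial RNA-processing enzyme (3R, 31404482 to 31404872, signal 1261), followed. The list went on with an intronic site of the kinase gene Lk6 (3R, 11760852 to 11761251, signal 1244) and a promoter site of Chro, which encodes the chromatin protein Chromator (3L, 22878713 to 22879101, signal 1094). Of the 25 highest IDR peaks, 17 had their summit within 500 bp of a TSS, 5 lay in introns, 2 were intergenic and 1 lay in another exon. The rest of these 25 had pooled signals between 714 and 1050. Their nearest protein-coding TSSs were those of px, CG1888, CG9663, larp, the Polycomb group gene ph-p, CenG1A, CG32772 and CG9147. Others were those of the mitochondrial ribosomal protein genes mRpS10 and mRpL41, GstE13, CG31145, tara, CG17896, CG11309, CG18549 and, at separate sites, CG4004. The CG4004 summits lay 5122 and 6052 bp from its TSS, with another annotated TSS at 428 and 502 bp. The tara summit lay 3171 bp away, with another annotated TSS at 915 bp. All 25 were found in both replicates, which both entered the derivation of the list, and all 25 had the higher signal in replicate 3.

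The strongest Groucho sites were recovered in both replicates, with the higher signal in replicate 3. At the CG14100 promoter the signal was 590 in replicate 1 and 1016 in replicate 3, and at the Ugalt promoter it was 475 and 910. In the highest quartile of IDR peaks by pooled signal, 81.0% had the higher signal in replicate 3, against 55.6% in the lowest quartile. When the 4492 highest regions of each replicate were compared, 3131 of those of replicate 1 overlapped one of replicate 3, or 69.7% (Wilson interval 68.3 to 71.0%). Random placement on the same arms gave 2.58 ± 0.239% (SD over 1000 placements) and at most 3.36%, a two-sided permutation p of 0.002, the smallest that 1000 placements can give. Of the IDR peaks, 4473 (99.6%) overlapped a region in both full replicate lists of 30000, and 3099 (69.0%) overlapped the top lists of both. Both replicates entered the derivation of the IDR peaks, so neither share is an independent test of their agreement. Across the 21509 replicate 1 regions matched in replicate 3, the signals correlated with Spearman's rho of 0.559 and Pearson's r of 0.670 on the log2 scale. Across the 4473 matched IDR peaks these were 0.462 and 0.60. The IDR peaks are the regions of highest pooled signal, a narrower range, so their lower values do not show poorer agreement. These correlations run across regions, which are not independent replicates, so no p was computed.

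**Figure D1:**
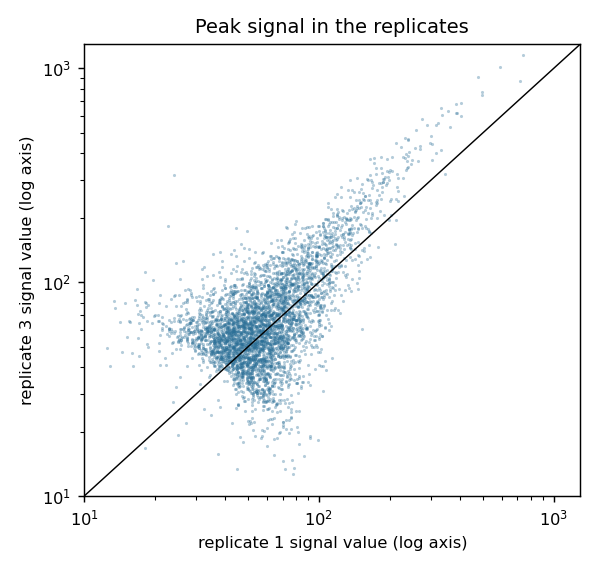
Signal value of each IDR peak in replicate 1 (horizontal, log axis) and replicate 3 (vertical, log axis), for the 4473 IDR peaks found in both; the line marks equal values. Most of the highest peaks lie above the line, and the median ratio of replicate 3 to replicate 1 was 1.17.

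Groucho sites were concentrated at promoters and scarce in coding sequence. Of the 4492 IDR summits, 2814 lay within 500 bp of an annotated TSS, or 62.6% (Wilson interval 61.2 to 64.0%), against 13.6 ± 0.531% (SD) of randomly placed summits. The summit of the RpL7 promoter site lay 5 bp from a TSS, the summit of the highest site of Eip75B, an ecdysone-induced nuclear receptor gene, lay 6 bp from one, and the median summit was 180 bp away. Introns held 27.1% of summits against 39.4% at random, and intergenic sequence held 7.90% against 27.3%. Coding sequence held 10 summits, 0.223% against 13.8% at random, and 3′ UTRs held 0.735% against 4.39%. These 5 classes each had a permutation p of 0.002, the smallest that 1000 placements can give, or 0.0028 after adjustment over 7 classes, while 5′ UTRs (0.712%, adjusted p = 0.763) and other exons (0.712%, adjusted p = 0.550) did not pass. Away from promoters, 375 summits (8.35%) lay over 5 kb from any TSS. The promoter enrichment was 4.59-fold over random placement, 7.30-fold with a 250 bp limit and 3.03-fold with 1000 bp. It was 2.12-fold over the 25508 pooled regions below the IDR threshold, of which 29.5% lay within 500 bp of a TSS, a background chosen after seeing the data. Against that background 5′ UTRs passed as lower (0.564 times, two-sided Fisher's exact test, adjusted exact p = 0.00141).

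**Figure D2:**
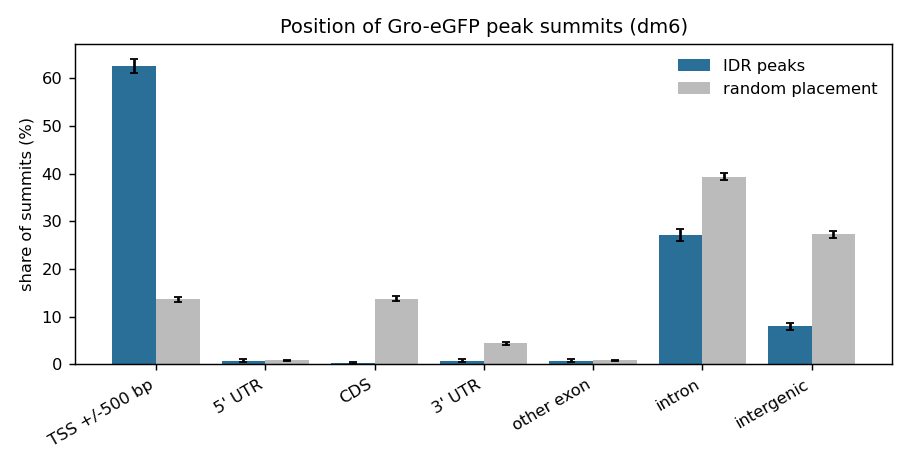
Share of IDR peak summits in each annotation class (percent of 4492 summits; error bars, 95% Wilson intervals) beside the mean of 1000 random placements (error bars, SD). Summits within 500 bp of a TSS made up 62.6% of IDR peaks and 13.6% of random positions.

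The dot-like chromosome 4 held few Groucho sites for its length, and the large autosomal arms 2L and 2R held slightly more than their share. Chromosome 4 had 18 IDR peaks, 13.5 per Mb, 0.402 times the share of its length (exact binomial test, two-sided, adjusted exact p = 4.93e-05). The X had 30.7 per Mb (0.914 times, adjusted exact p = 0.0217), and 2L and 2R had 36.1 per Mb each (1.08 and 1.07 times, adjusted exact p = 0.0311 for both). Arms 3L (32.9 per Mb, adjusted exact p = 0.597) and 3R (33.3 per Mb, adjusted exact p = 0.753) did not pass. With the number of protein-coding genes per arm in place of length, 0 of the 6 arms passed, and chromosome 4 stood at 0.698 times its share (adjusted exact p = 0.414). Without replicate 1, the X (0.968, adjusted exact p = 0.409) and 2R (1.03, adjusted exact p = 0.409) no longer passed; in the upper part of the list by signal, chromosome 4 alone did; and against pooled regions below the IDR threshold, chromosome 4 stood at 0.223 times its share. Against these regions 2L no longer passed (1.04 times, adjusted exact p = 0.182), 3L passed as lower (0.917 times, adjusted exact p = 0.00558) and 3R as higher (1.06 times, adjusted exact p = 0.0382).

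Most ribosomal protein genes had a Groucho site near a TSS. No immunoprecipitation from untagged embryos was analysed, so recovery at any highly transcribed locus cannot be told apart from binding. Of 82 genes for cytosolic ribosomal proteins, 63 (76.8%, Wilson interval 66.6 to 84.6%) had an IDR summit within 1 kb of a TSS, against 25.6% of other protein-coding genes. The odds ratio was 9.64 (two-sided Fisher's exact test, 95% interval 5.68 to 17.1, adjusted exact p = 1.58e-20). Among them, pooled signals reached 466 at RpL7, 443 at RpL32, 386 at RpL23A and 379 at RpS27, where replicate signals were 230 ± 22.3, 224 ± 29.3, 192 ± 45.6 and 189 ± 30.3 (SD, n = 2). The 63 genes also had high peaks, with a median of the highest signal of 179 against 125 over all genes with a peak, percentile 100 among 10000 random lists of that size. The odds ratio moved with the handling of shared promoters. It was 2.95 (adjusted exact p = 0.000573) when summits near the TSSs of more than 1 gene were left out. In that setting it was 5.15 for Polycomb and Trithorax group, 4.36 for ecdysone response, 4.0 for EGFR and FGF and 4.0 for Dpp pathway genes. The setting takes out summits and keeps all genes, so it favours lists of genes without close neighbours. Its odds ratios therefore do not rank these lists. For ribosomal protein genes the odds ratio was 5.16 against genes that hold a pooled region and 14.7 over all pooled regions (a set chosen after seeing the data). It was 9.24 and 11.3 in the single-replicate lists.

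Polycomb and Trithorax group genes, which encode chromatin regulators that keep developmental genes silent or active, carried Groucho sites as well. Of 23 such genes, 16 (69.6%, Wilson interval 49.1 to 84.4%) had an IDR summit within 1 kb of a TSS (odds ratio 6.56, 95% interval 2.55 to 18.9, adjusted exact p = 9.51e-05). The highest was ph-p with a pooled signal of 968, followed by Trl, which encodes GAGA factor, with 238, the remodeller gene brm with 217 and Psc with 174. Their replicate signals were 491 ± 226, 126 ± 76.6, 109 ± 4.68 and 86.8 ± 7.66 (SD, n = 2). Also among the 16 were Pc, trx, kis, mor, osa, Su(z)2, Su(z)12 and ph-d, while pho, phol, ash1, ash2, Asx, Sce and escl had none. The odds ratio ranged from 4.35, in the upper part of the list by signal, to 7.81, over gene bodies with 1 kb on either side.

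Genes for cuticle proteins and for chemosensory receptors held almost no sites. Of 117 cuticle protein genes, 2 had an IDR summit within 1 kb of a TSS (1.71%, odds ratio 0.0492, adjusted exact p = 7.86e-12), as did 3 of 119 odorant and gustatory receptor genes (2.52%, odds ratio 0.0732, adjusted exact p = 4.67e-11). Each of these 5 summits lay closer to the TSS of another gene. The cuticle genes were Cpr60D, whose site was nearest to CG30161, and Cpr73D, whose site was nearest to Ogdh. The receptor genes were Or9a, Gr63a and Or88a, with sites nearest to Neb-cGP, Lamtor4 and CG12402. Among genes that hold a pooled region, 3 of 10 receptor genes had an IDR summit and the call ended (odds ratio 0.519, adjusted exact p = 0.996), whereas 2 of 25 cuticle genes did (odds ratio 0.105, adjusted exact p = 0.00102). Over the other settings the odds ratio ran from 0 to 0.20 for cuticle genes, with 0.0250 without replicate 1, and from 0 to 0.127 for receptor genes, the latter without replicate 3.

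Several signalling pathways had sites at well-known members without passing the test over the 27 gene lists. In the Dpp pathway, which transmits BMP signals, 9 of 18 genes had a summit within 1 kb of a TSS (adjusted exact p = 0.129), with pooled signals of 411 at shn, 156 at dally, 152 at Mad and 130 at dlp. In the EGFR and FGF pathway it was 10 of 24 genes (adjusted exact p = 0.337), among them spi with 424, Ras85D with 231, aop with 230 and sty with 172. Both pathways passed in each replicate list alone, with odds ratios of 4.62 and 3.65 (adjusted exact p = 0.00772 and 0.0343) for Dpp and of 2.94 and 2.92 (adjusted exact p = 0.0409 and 0.0371) for EGFR and FGF, without replicate 1 and without replicate 3. By the nearest TSS at any distance, a rule not corrected for the sequence nearest to each gene, they also passed (odds ratio 4.31 and 4.08, adjusted exact p = 0.00912 and 0.00393). They passed with shared summits left out too (adjusted exact p = 0.0416 and 0.0180), a setting that favours genes without close neighbours. Neither passed against random lists matched on gene span and TSS number (fold 1.34 and 1.12, adjusted permutation p = 0.616 and 1) or among genes that hold a pooled region (odds ratio 1.82 and 1.01, adjusted exact p = 0.996 and 1). In the upper part of the list by signal Dpp stood at 1.61 (adjusted exact p = 0.756) and EGFR and FGF at 3.39 (adjusted exact p = 0.0326). The Wingless pathway had 9 of 25 (adjusted exact p = 0.526), led by sgg with 401 and nkd with 201, and ecdysone response genes had 7 of 17 (adjusted exact p = 0.411), led by Eip75B with 287 and E23 with 231. By the nearest TSS both passed (odds ratio 2.71 and 4.93, adjusted exact p = 0.0464 and 0.00592), and ecdysone response genes did so with shared summits left out (adjusted exact p = 0.0357). Neither passed against matched random lists (fold 1.02 and 0.882, adjusted permutation p = 1 for both) or among genes that hold a pooled region (odds ratio 0.909 and 1.21, adjusted exact p = 1 for both). The Notch pathway list had 8 of 22 (adjusted exact p = 0.526), with kuz at 262, Nct at 206, neur at 157 and mib1 at 129. The summits counted for kuz, Nct and neur lay nearest to the TSSs of B4, CG7006 and hyx, and the count includes her, a sex determination gene placed in the list by mistake.

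Lists of patterning and cell fate genes had counts near or below that of other genes, and none passed. The counts were 2 of 12 for the E(spl) complex (adjusted exact p = 0.829), 6 of 31 for repressors known to recruit Groucho (adjusted exact p = 0.661), 4 of 20 for gap and pair-rule genes (adjusted exact p = 0.829) and 2 of 15 for segment polarity genes (adjusted exact p = 0.526). They were 0 of 8 for the Hox genes (Wilson interval 0 to 32.4%, adjusted exact p = 0.367), 5 of 27 for dorsal-ventral patterning (adjusted exact p = 0.656), 4 of 25 for proneural and neuroblast genes (adjusted exact p = 0.526) and 4 of 18 for trachea and ectoderm appendage genes (adjusted exact p = 1). Sites within these lists included E(spl)mbeta-HLH at 139, E(spl)m3-HLH at 131, bowl at 200, cic at 169, elav at 347 and cad at 102. Mesoderm and muscle genes had 3 of 25 (adjusted exact p = 0.411), namely Tm1 at 105, Mef2 at 98.7 and tin at 80.9; against matched random lists this count was lower (fold 0.323, adjusted permutation p = 0.0252). Several of these odds ratios crossed 1 under other settings without passing the test. With shared summits left out they were 1.60 for the E(spl) complex, 1.92 for the repressors, 2.0 for gap and pair-rule genes and 1.81 for dorsal-ventral patterning. That setting favours genes without close neighbours. Gap and pair-rule genes stood at 0.154 without replicate 1, 0.972 without replicate 3 and 0 in the upper part of the list by signal, also without passing.

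Lists of general cellular functions and of other cell types gave the remaining counts. Oxidative phosphorylation genes had 30 of 80 (odds ratio 1.72, adjusted exact p = 0.114), which passed against matched random lists (fold 1.59, adjusted permutation p = 0.0216) and without replicate 3 (odds ratio 1.85, adjusted exact p = 0.0371). With shared summits left out their odds ratio was 0.885, and among genes that hold a pooled region it was 1.07 (adjusted exact p = 1). Proteasome genes had 16 of 48 (adjusted exact p = 0.526), cell cycle genes 8 of 22 (adjusted exact p = 0.526; 0.0144 by the nearest TSS, but 1 against matched lists and among genes with a pooled region), stress response genes 11 of 55 (adjusted exact p = 0.526) and germ line genes 5 of 18 (adjusted exact p = 0.829). Hemocyte and fat body genes had 2 of 15 (adjusted exact p = 0.526), photoreceptor genes 3 of 17 (adjusted exact p = 0.686) and Jonah protease genes 2 of 16 (adjusted exact p = 0.526). The chorion and yolk list had 1 of 19 (adjusted exact p = 0.143), and that gene was Cp190, which encodes an insulator protein and not a chorion protein. Over all pooled regions, a set chosen after seeing the data, oxidative phosphorylation (odds ratio 2.996, adjusted exact p = 0.000146), cell cycle (4.73, adjusted exact p = 0.0163), EGFR and FGF (8.22, adjusted exact p = 0.00173) and Wingless genes (3.92, adjusted exact p = 0.0200) passed as higher. The chorion and yolk (odds ratio 0.198, adjusted exact p = 0.0082) and hemocyte and fat body lists (0.186, adjusted exact p = 0.0198) passed there as lower. Of the 27 lists, 4 passed after adjustment and 7 had an unadjusted p under 0.05.

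**Figure D3:**
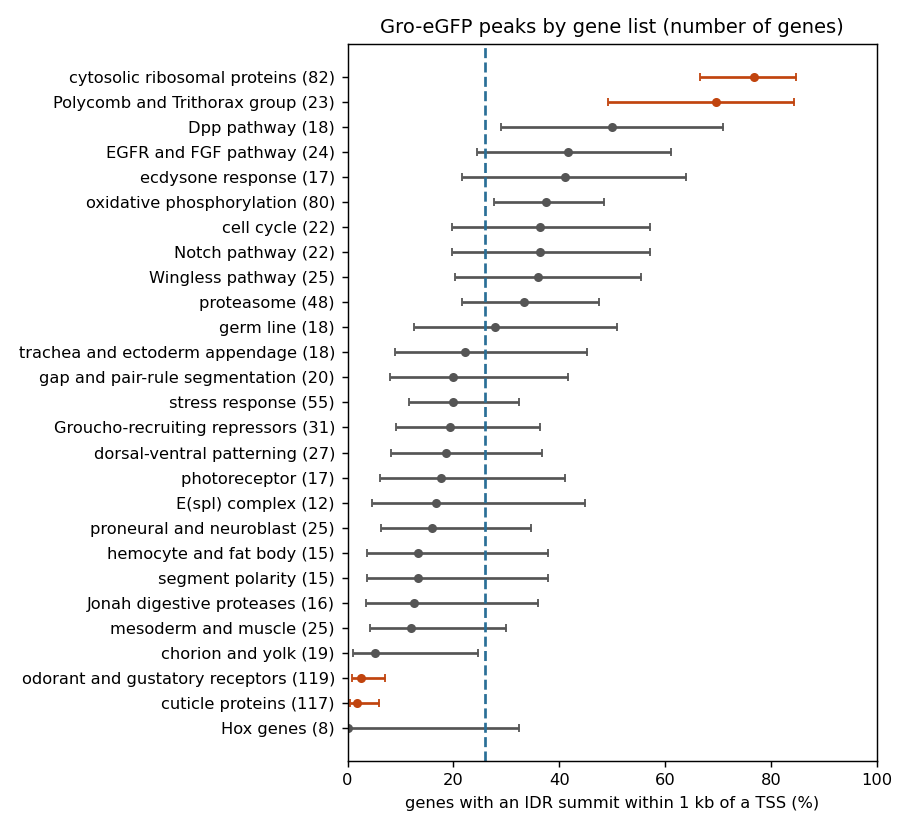
Share of each list's genes with an IDR summit within 1 kb of a TSS (percent; points, list share; error bars, 95% Wilson intervals; number of genes in parentheses; dashed line, 25.9% over all 13945 protein-coding genes). The lists that passed, in orange, are ribosomal proteins at 76.8%, Polycomb and Trithorax group genes at 69.6%, receptors at 2.52% and cuticle proteins at 1.71%.

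Most panel targets and partners of Groucho had no IDR peak within 5 kb, while gro itself carried one of the strongest. The gro promoter site had a pooled signal of 682 (rank 32) and a replicate signal of 338 ± 49.1 (SD, n = 2); the labels do not say whether the transgenic insertion adds a copy of gro, so the copy number of this interval is not known. The panel fixed in advance held 43 targets and partners of Groucho, and 14 of them (32.6%) had an IDR summit in the gene or within 5 kb, against 6891 (49.4%) of all protein-coding genes, a difference that was not tested. Besides gro these were E(spl)mbeta-HLH at 139, the Notch receptor gene N at 156, the pair-rule gene hry at 109, the Dpp target repressor brk at 108, sog at 115.4, tup at 160, Antp at 150, pnt at 155, sty at 172, aos at 118, dpp at 91.2 and inv at 80.8. The gene E(spl)m8-HLH counted through the gro peak. The 5 kb window takes in promoters of neighbouring genes in this way. It favours genes with close neighbours, which limits the comparison of the panel with all protein-coding genes. The highest peak of N lay nearest to the TSS of CG18508 and that of tup nearest to CG10602. No IDR peak lay within 5 kb of Delta, E(spl)mdelta-HLH, en, wg, hh, zen, tld, vnd, ind, Dr, rho, Ubx, Dll, salm, vg, tll, hkb, Kr, kni, gt, eve, ftz, run, odd, slp1, dpn, pros, twi or sna. Of these, en, Ubx and wg had pooled regions of 79.0, 77.9 and 76.4, just under the lowest IDR signal, and 32 of the 43 had a pooled region of any height. Among 5 housekeeping genes, RpL32 at 443, eEF1alpha1 at 282, Act5C at 267 and alphaTub84B at 221 had an IDR peak, and Gapdh1 had none; the peak of eEF1alpha1 lay nearest to the TSS of ERp60.

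Some genes had many Groucho sites in the gene or within 5 kb, a count that was not compared with that expected for their span. The transcription regulator gene sbb had 16 IDR summits in the gene or within 5 kb. The genes ush, shn and Eip75B had 13 each, while tara, Raf, CHES-1-like and CG1677 had 12 and bun and msn had 11. The highest peaks of these genes ranged from 213 at msn to 1892 at ush; those assigned to sbb, ush, CG1677 and msn lay nearest to the TSSs of CG14502, cbt, CBP and RpL8. In all, 242 genes had 5 or more summits. That number was 73 when summits inside the gene alone were counted and 38 in the upper part of the list by signal. The count of CG1677 includes the promoter summits of brk, which lies within the span of CG1677.

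Elements of housekeeping promoters were more frequent at Groucho sites than in flanking sequence and, by a smaller ratio, more frequent than at promoters below the IDR threshold. The DREF element TATCGATA was present in 6.37% of windows of 100 bp on either side of the 4492 summits. In windows 1000 bp downstream, toward the higher coordinate, it was present in 0.735% (ratio 8.67, exact McNemar test, two-sided, adjusted exact p = 5.73e-51). Motif 1, GGTCACACT, was present in 3.38% against 0.289% (ratio 11.7, adjusted exact p = 1.04e-30), and the paired CGATA sites of the insulator protein BEAF-32 in 0.712% against 0.0668% (ratio 10.7, adjusted exact p = 1.6e-06). The Ohler 5 element CAGCTGTT stood at 4.67% against 2.16% (ratio 2.16, adjusted exact p = 3.12e-10). Over the planned settings except distal summits, the ratio stayed between 6.51 and 15.3 for DREF, 4.22 and 18.4 for Motif 1, 5 and 30 for BEAF-32, and 2.02 and 10 for Ohler 5. Among the 1261 summits over 1 kb from a TSS, DREF and Motif 1 had a ratio of 1 and Ohler 5 of 0.739, and none of these passed. Since most summits lie at promoters, the 2814 promoter summits were also compared, after seeing the data, with 6014 promoter summits of pooled regions below the IDR threshold and over 1 kb from an IDR summit (Fisher's exact test, two-sided). DREF was present in 9.77% against 5.00% (ratio 1.95, adjusted exact p = 6.98e-15), and the ratio was 1.41 for Motif 1 (adjusted exact p = 0.00656), 2.21 for BEAF-32 (adjusted exact p = 0.0132) and 1.38 for Ohler 5 (adjusted exact p = 0.00447). Within 250 bp of the outermost TSS, DREF was present in 16.2% of 3612 genes with a site and 7.69% of 10333 genes without (ratio 2.11, adjusted exact p = 1.36e-43).

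Motifs of developmental regulators differed less between summits and flanks. A forkhead motif of the Sloppy-paired type was present in 16.6% against 12.3% of windows (ratio 1.35, adjusted exact p = 4.88e-08), GAGA repeats in 6.23% against 4.14% (ratio 1.51, adjusted exact p = 1.58e-05) and GATA sites in 36.2% against 31.6% (ratio 1.14, adjusted exact p = 1.58e-05). The Huckebein/Sp motif was rarer at summits, 2.23% against 4.63% (ratio 0.481, adjusted exact p = 1.59e-09), and so was the Twist/proneural E box, 36.6% against 39.5% (ratio 0.928, adjusted exact p = 0.0151). The E box call ended without replicate 3 (ratio 0.980, adjusted exact p = 0.589), against flanks 1000 bp upstream (0.980, adjusted exact p = 0.693) or 5000 bp downstream (0.975, adjusted exact p = 0.460) and at distal summits (0.955, adjusted exact p = 0.898). Against its reversed sequence in the same windows the E box was more frequent (ratio 1.38, adjusted exact p = 9.29e-24). Against their reversed sequences, GATA (ratio 0.964, adjusted exact p = 0.207) and Huckebein/Sp (ratio 0.893, adjusted exact p = 0.363) did not pass; the GAGA motif reads the same when reversed, so that control was void for it. Against promoter summits below the IDR threshold, forkhead (ratio 1.06, adjusted exact p = 0.606), GAGA (1.21, adjusted exact p = 0.152), GATA (0.987, adjusted exact p = 1) and the E box (1.01, adjusted exact p = 1) did not pass, while Huckebein/Sp did (0.589, adjusted exact p = 0.00375). At TSSs of genes with a site against genes without, forkhead (ratio 1.2, adjusted exact p = 1.15e-09) and GAGA (1.39, adjusted exact p = 8.3e-07) passed as more frequent and Huckebein/Sp as rarer (0.823, adjusted exact p = 0.0326), while GATA (0.980, adjusted exact p = 0.296) and the E box (1.01, adjusted exact p = 0.463) did not pass. GAGA also did not pass in the upper part of the list by signal (ratio 1.32, adjusted exact p = 0.0776). At summits over 1 kb from a TSS GAGA did not pass (1.15, adjusted exact p = 0.902), nor did GATA at summits within 500 bp of one (1.05, adjusted exact p = 0.470).

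The C box CACGNG, bound by Hairy and E(spl) repressors that recruit Groucho, was as frequent in summit as in flanking windows, 16.0% against 15.9% (ratio 1.00, adjusted exact p = 1). It passed as more frequent without replicate 3 (ratio 1.14, adjusted exact p = 0.0172) and not without replicate 1 (ratio 0.960, adjusted exact p = 0.552), and it was rarer than its reversed sequence (ratio 0.592, adjusted exact p = 2.56e-40). It was more frequent at TSSs of genes with a site than of genes without (ratio 1.17, adjusted exact p = 6.27e-09), and not at promoter summits against those below the IDR threshold (ratio 1.09, adjusted exact p = 0.296). At TSSs of genes with a site Brinker (ratio 1.10, adjusted exact p = 3.02e-05) and Engrailed-type (1.07, adjusted exact p = 0.0454) motifs were more frequent too, and Initiator was rarer (0.806, adjusted exact p = 1.63e-22). Apart from the forkhead and Huckebein/Sp motifs, those of other Groucho partners did not pass against the main flank either, among them Brinker (21.1% against 21.4%), Engrailed-type homeodomains (11.9% against 12%), Runt (7.81% against 8.28%), Dorsal (6.63% against 6.70%) and Pangolin (14.5% against 14.1%). The Capicua motif, at 1.65% against 1.34% (ratio 1.23, adjusted exact p = 0.494), passed without replicate 1 (ratio 1.54, adjusted exact p = 0.0287), in windows of 200 bp (1.39, adjusted exact p = 0.00753) and against its reverse (2.0, adjusted exact p = 0.00131). Dorsal was rarer in windows of 200 bp (0.831, adjusted exact p = 0.00259) and more frequent than its reverse (1.77, adjusted exact p = 2.05e-09). Brinker also passed as more frequent than its reverse (1.11, adjusted exact p = 0.0230), and Pangolin passed as rarer than its reverse (0.881, adjusted exact p = 0.0193). The Nkx motif passed against upstream flanks (1.24, adjusted exact p = 0.0117) and its reverse (1.5, adjusted exact p = 6.3e-07), and Su(H) against upstream flanks (1.29, adjusted exact p = 0.0455). Initiator also passed against upstream flanks (1.13, adjusted exact p = 0.0195), its reverse and at promoters, T-box against flanks 5000 bp away (3.25, adjusted exact p = 0.0075), and Odd-skipped was rarer than its reverse (0.412, adjusted exact p = 0.0115). Against the main flank, 7 of the 23 motifs passed as more frequent at summits, 2 as less frequent, and 14 did not pass; the latter also held Su(H), Nkx, Odd-skipped, T-box, Zelda, Initiator and CTCF.

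**Figure D4:**
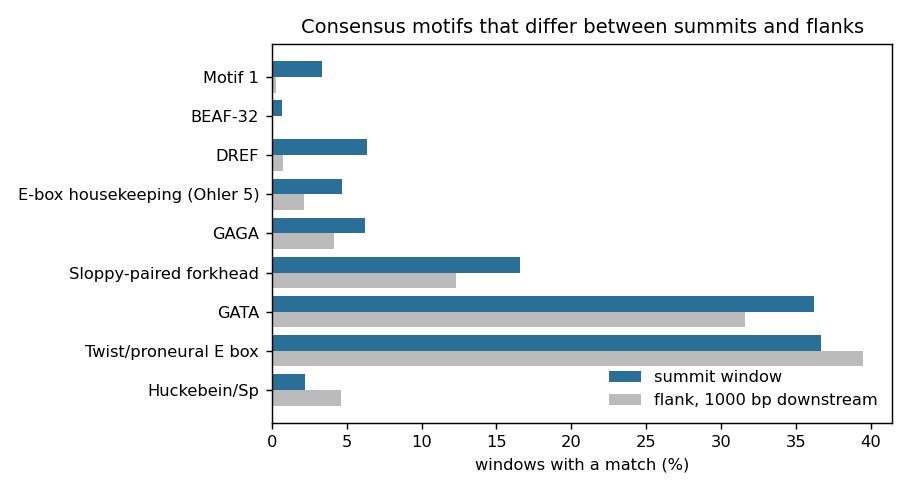
Share of windows with at least 1 match (percent) for the 9 motifs that passed, at summits (blue) and 1000 bp downstream by coordinate (grey), over 4492 windows each. DREF stood at 6.37% against 0.735% and Motif 1 at 3.38% against 0.289%.

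Both genome builds gave nearly the same number of peaks and overlap of replicates. Annotation classes, gene lists and motifs were examined in dm6 alone. The IDR list held 4536 regions in dm3 and 4492 in dm6, with a median signal of 115.1 and 115.9. Chromosome 4 had 18 IDR peaks in either build, and the other arms differed by at most a ratio of 0.981 of dm6 to dm3. The top lists of the replicates overlapped by 69.8% in dm3 against 69.7% in dm6. Coordinates were not converted, so single sites were not compared between builds.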

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

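The backgrounds of pooled regions and of genes without a site, all pooled regions in place of IDR peaks for gene lists, and the stricter and single-replicate lists for peak heights, multi-peak genes and named genes, were chosen after the results were seen; the other settings were planned. Over all settings the promoter enrichment stayed between 2.12 and 7.30-fold, and the overlap of top regions between 61.0 and 71.8%, each past its test; with 10000 top regions 100 placements gave a permutation p of 0.0198, the smallest they can give. The ribosomal protein, Polycomb and cuticle lists passed in the same direction in every setting. Of the values for single classes, arms, lists and motifs, 428 kept their direction and side of the threshold, 22 stopped passing, 40 began to pass and 102 crossed 1, most of them lists and motifs that passed neither before nor after. The depth of the libraries is unknown, so no limit from depth can be given. The CTCF motif had 0 flank matches and gave no ratio to compare. The cause of the changes below was not tested, except where fewer or more regions or summits were counted by construction.

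The Spearman correlation was 0.462 over IDR peaks and 0.599 with a reciprocal overlap of 50%. The number of arms that passed was 1 in the stricter list, 0 against genes per arm, and 2 to 4 without a replicate. The number of lists that passed was 9 by the nearest TSS, 7 with shared summits left out, 10 over all pooled regions, and 6 to 7 without a replicate. The number of lists with unusual height was 3 over pooled regions and 2 to 5 without a replicate, against 1. Reversed motifs gave 14 motifs that passed, distal summits 3 and promoter summits against those below the IDR threshold 5, against 9. Genes with 5 or more summits numbered 73 in gene bodies alone and 38 in the stricter list.

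Without a replicate, the fold ranged from 0.810 to 1.03 for 5′ UTRs and 0.976 to 1.02 for arm 3R. The odds ratio ranged from 0.564 to 1.01 for Groucho-recruiting repressors, 0.662 to 1.03 for dorsal-ventral patterning, 0.587 to 1.46 for germ line, 0.729 to 1.07 for segment polarity and 0.838 to 1.12 for trachea. The motif ratio ranged from 0.973 to 1.06 for Brinker, 0.980 to 1.01 for Dorsal, 1.00 to 1.02 for Engrailed, 0.960 to 1.14 for the C box, 0.929 to 1.05 for Odd-skipped and 0.917 to 1.21 for T-box.

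Arms against genes per arm stood at 0.993 for 2L, 0.994 for 2R, 1.05 for 3L and 1.02 for the X; 3R stood at 1.06 against sub-threshold pooled regions and at 1.02 in the stricter list. In that list the odds ratio was 1.13 for the E(spl) complex, and motif ratios were 1.19 for Dorsal, 1.10 for Engrailed, 0.975 for the C box, 1.38 for Odd-skipped, 0.958 for Pangolin and 0.733 for T-box.

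Odds ratios by the nearest TSS at any distance were 1.15 for the E(spl) complex, 1.41 for Groucho-recruiting repressors, 1.15 for Hox genes, 1.72 for dorsal-ventral patterning, 1.86 for gap and pair-rule genes, 0.688 for germ line, 1.34 for mesoderm and muscle, 1.09 for proneural genes, 1.72 for segment polarity and 2.19 for trachea. With shared summits left out they were 1.60 for the E(spl) complex, 1.92 for Groucho-recruiting repressors, 1.14 for Jonah proteases, 1.81 for dorsal-ventral patterning, 2.0 for gap and pair-rule genes, 0.997 for germ line, 1.23 for hemocytes, 0.885 for oxidative phosphorylation, 1.71 for photoreceptor, 1.09 for proneural genes and 2.28 for trachea. Over all pooled regions they were 1.04 for the E(spl) complex, 2.98 for segment polarity and 1.49 for trachea. Against genes with a pooled region they were 0.909 for Wingless, 0.881 for cell cycle, 0.757 for germ line, 2.43 for hemocytes and 1.82 for photoreceptor. Germ line stood at 0.672 with TSSs within 500 bp and 0.831 over gene bodies, where trachea stood at 1.08. Folds over matched lists were 1.24 for the E(spl) complex, 0.998 for cell cycle, 0.882 for ecdysone response and 0.897 for germ line.

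Motif ratios against the reversed motif were 1.11 for Brinker, 1.77 for Dorsal, 1.03 for Engrailed, 0.964 for GATA, 0.592 for the C box, 0.881 for Pangolin, 0.896 for Su(H), 0.839 for T-box and 1.38 for the E box. At distal summits they were 1.12 for Brinker, 0.739 for Ohler 5, 0.955 for the C box and 0.893 for Initiator, and at promoter summits 1.08 for Dorsal, 1.07 for Engrailed and 1.03 for Runt. Windows of 50 bp gave 1.04 for Brinker and 0.953 for Pangolin, and windows of 200 bp 1.02 for Brinker and 1.09 for Engrailed. The upstream flank gave 0.902 for Capicua, 1.05 for Engrailed and 1.08 for Odd-skipped, and the flank 5000 bp away 1.02 for Brinker and 0.991 for Pangolin.

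At promoter summits against those below the IDR threshold, motif ratios were 0.859 for Capicua, 0.925 for Pangolin, 1.01 for Odd-skipped, 1.01 for the E box, 0.987 for GATA and 0.917 for Initiator. At TSSs of genes with a site against genes without they were 1.07 for Engrailed, 1.10 for Brinker, 0.974 for Capicua, 0.974 for Pangolin, 1.39 for Odd-skipped, 1.01 for the E box, 0.980 for GATA and 0.806 for Initiator.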

Other observations

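Chosen after the results were seen were the 9 added gene lists, the 7-mer counts, the comparison of promoter with distal motifs, the unions of patterning lists, the motif comparison with promoters below the IDR threshold, the replicate ratios by signal, the tests of promoter GC content, of gene span, of the nearest TSS, of neighbouring promoters and of a scale factor, and the split of tRNA genes by distance. Translation initiation factor and nucleoporin genes carried Groucho sites often, mostly through summits shared with a neighbour. Of 44 translation initiation factor genes, 24 had an IDR summit within 1 kb of a TSS (odds ratio 3.45, Fisher's exact test, adjusted p over the 9 lists = 0.000354), with pooled signals of 1387 at eIF2Bbeta, which shares the Ugalt site, 701 at eIF6 and 231 at eIF3h. Of 21 nucleoporin genes, 12 did (odds ratio 3.82, adjusted exact p = 0.00419), led by Nup37 at 379, which shares the RpS27 site, and Nup160 at 252. With summits near more than 1 gene left out, these lists had 8 (odds ratio 1.78, adjusted exact p = 0.205) and 0 genes with a site (adjusted exact p = 0.205). Genes for insulator and promoter architectural proteins had 10 of 13 (odds ratio 9.56, adjusted exact p = 0.000519; 4.70 without replicate 1, adjusted exact p = 0.0182), with 1094 at Chro, 243 at Dref and 127 at BEAF-32; with shared summits left out it had 4 (odds ratio 3.55, adjusted exact p = 0.109). Sites at Chro, Trl and Cp190 had been seen before this list was drawn up, so its p is not independent evidence. Ionotropic receptor genes had 1 of 60 (odds ratio 0.0482, adjusted exact p = 6.63e-06) and the Osiris family, expressed in the cuticle-forming epidermis, 0 of 25 (Wilson interval up to 13.3%, adjusted exact p = 0.00197; odds ratio 0.122 without replicate 1). Mitochondrial ribosomal protein genes had 25 of 73 (adjusted exact p = 0.145), above matched random lists (fold 2.19, adjusted permutation p = 0.0018) and with an adjusted exact p of 0.046 without replicate 3. With shared summits left out they had 1 (odds ratio 0.110, adjusted exact p = 0.0185). That setting took out their shared sites by rule and kept the genes, so the low count shows no lack of sites. The counts were 11 of 33 for aminoacyl-tRNA synthetases (adjusted exact p = 0.364), 10 of 25 for Mediator subunits (adjusted exact p = 0.145) and 4 of 15 for TBP-associated factors (adjusted exact p = 1).

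Promoter and distal Groucho sites differed in sequence, as promoters do from other sequence: against promoters below the IDR threshold the DREF ratio was 1.95. DREF was enriched over flanks 15.3-fold at the 2814 promoter summits and 1.00-fold at 1261 distal ones (adjusted exact p of the difference = 0.000164), Motif 1 18.4-fold and 1.00-fold (0.00741), and Ohler 5 2.84-fold and 0.739-fold (0.000329). GATA sites went the other way, in 43.3% of distal windows against 32.3% of their flanks (1.34-fold; 1.05-fold at promoters; adjusted exact p of the difference = 0.000329), and at 1.24 times their reversed sequence. GAGA repeats were enriched 1.80-fold and 1.15-fold (0.0419), while BEAF-32, forkhead, Huckebein/Sp and E box motifs showed no difference that passed. Of 8192 7-mers counted on arms 2L, 2R and X, 349 were more frequent at summits and 539 less frequent. The highest, ATCGATA, was in 12.8% of windows against 2.54% of flanks, and in 12.5% against 3.09% on the arms held out; AACACTG stood at 6.80% against 1.73%, and 6.47% against 2.19% held out. All 12 highest 7-mers passed on the held-out arms.

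Ribosomal protein genes passed in the main comparison, and the proteasome, oxidative phosphorylation and aminoacyl-tRNA synthetase lists did not. The proteasome and oxidative phosphorylation lists hold paralogs without a site, such as Prosbeta4R1, Prosalpha6T, COX4L and ND-24L. The ribosomal protein list holds some too, such as RpS5b and RpS19b. Shares therefore depend on which paralogs a list holds, and lists without paralogs were not tested. Translation initiation factor (odds ratio 3.45) and nucleoporin genes (3.82) passed among the 9 added lists, mostly through shared summits. The pattern at ribosomal protein genes was set against 4 technical explanations. No biological explanation was tested, since the series holds 1 group. The pattern did not rest on 1 replicate alone, as the odds ratio of ribosomal protein genes was 9.24 or more in either (adjusted exact p of 5.05e-20 or less). GC content, gene span and number of TSSs were argued against. Ribosomal protein genes exceeded lists matched on GC content within 500 bp of their TSSs 3.01-fold (permutation p = 0.0002, the smallest that 10000 lists can give). They exceeded lists matched on span and TSS number 2.72-fold (adjusted permutation p = 0.0018). Promoters shared with a neighbour were not among the 4 explanations, and the odds ratio fell with shared summits left out, as given above. Recovery at any highly transcribed locus, a candidate explanation, cannot be told apart: 25 of 290 tRNA genes had a summit within 500 bp, 2.37 times the random count of 10.5 (permutation p = 0.0120), as was predicted for it before the result was seen, but the 210 tRNA genes over 1 kb from a coding TSS had 7 against 7.70 (0.909 times, 95% interval 0.365 to 1.87), and 18 of the 80 nearer ones did. An immunoprecipitation from untagged embryos, which would test it, was not analysed here.

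Whether patterning genes hold few sites was not settled. Of the 150 genes in all 9 patterning and cell fate lists, 27 had a summit within 1 kb of a TSS (odds ratio 0.625, 95% interval 0.395 to 0.956). By the nearest TSS at any distance 48 did (1.63, 1.13 to 2.32), but that rule favours genes with much sequence nearest to them. For the 150 genes it was not corrected for this, and no list passed alone by either rule. The 9 lists were joined after their counts were seen, so neither odds ratio of the 150 genes is a test. The following values are for 116 genes of 7 lists, without mesoderm and trachea, joined after these were seen to be low, so that their odds ratio of 0.594 is no test. Promoters shared by neighbouring genes cannot be told apart as a cause. With shared summits left out the odds ratio was 1.47 (0.834 to 2.45), and among genes with no other coding TSS within 2 kb it was 0.953 (0.518 to 1.65). The former setting keeps all genes and so favours those without close neighbours. No other coding TSS lay within 2 kb for 101 of the 116 patterning genes, against 5471 of all 13945 protein-coding genes. Sites away from the TSS stay open. Summits in the gene or within 5 kb stood at 0.665 times matched lists, and summits within 1 kb of a TSS at 0.550 times. The former met the bound set in advance against sites away from the TSS. That bound was wrong, since promoters of neighbours count too. Nearest summits stood at 1.01 times lists matched on the sequence nearest to each gene. That sequence had a median of 16.6 kb for the patterning genes and 4.29 kb for other genes. A threshold that is too strict stays open, since over all pooled regions the odds ratio was 0.825 (0.563 to 1.21), as may dilution of sites used in few cells or for a short time, which was not tested.

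Peak height differed between the replicates by more than 1 constant factor on the whole signal. The median ratio of replicate 3 to replicate 1 was 1.07, 1.08, 1.13 and 1.34 from the lowest to the highest quartile of signal, and 1.26 in introns against 1.13 at promoters. A single scale factor on the whole signal was argued against. The median log2 ratio was 0.40 in the 448 peaks highest in replicate 1 and 0.20 in the other 4025. The difference was 0.202 (bootstrap 95% interval 0.146 to 0.263), where noise in replicate 1 would lower the ratio of the highest peaks. A factor on the signal above a common background was not tested. GC content cannot be told apart as a cause: the rank correlation of the log2 ratio with GC content was −0.265 across peaks, between the bounds set in advance. A difference in preparation cannot be told apart from the replicates, as the labels give each a protocol document of its own; no biological explanation was tested, since both are of 1 group.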
